A study of Arabidopsis thaliana with 12 samples.

How the data were processed

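RNA from roots and shoots of Arabidopsis thaliana seedlings carrying an estradiol-inducible CLE3 transgene was measured on 12 one-colour Affymetrix whole-transcript arrays. CLE3 encodes a small secreted signalling peptide of the CLE family. Estradiol switches the transgene on, and DMSO is the solvent control. Per the labels, roots of 7 day old plants were exposed for 24 h to estradiol or to DMSO, and roots and shoots were then collected separately. The dose is 5 mM as the labels give it. Micromolar doses are usual for this inducer, and the unit was not checked here. Groups and replicate numbers were taken from the sample titles, which gave 4 groups of 3 arrays. Another label field, the source name, gave estradiol for every root array and DMSO for every shoot array, and it was not used. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

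The deposited table held 1 value per feature and array for 38408 features. Per the submitters' processing notes, the authors used Affymetrix Expression Console 1.3. The settings of that step are not given in the sources used here. The deposited values were taken as log2 expression because they lay between 0.19 and 13.84, a scale that no label states, and whether the table was also centred is not given. Array medians lay between 4.99 and 5.09. The number of arrays limits the precision, and no signal over background was part of the table.

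Features were named through the platform annotation, updated by gene identifier with the RefSeq gene table of assembly TAIR10.1. Of the 38408 features, 16722 had 1 gene, 759 had several and 20927 were not listed and stay unnamed here. Among features with 1 gene, 16574 matched the gene table, and 16505 distinct genes resulted. Each gene was represented by its feature with the highest mean over all arrays, and no gene was named from a feature with several genes. No listed feature named CLE3 or WRKY33, so the level of the induced gene was not analysed here. Values identical to those of another feature on every array were found for 7132 features.

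A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no intensity trend). The contrasts were estradiol minus DMSO in roots, the same in shoots, the difference between these effects (shoots minus roots), and root minus shoot under DMSO. P-values were adjusted by the Benjamini-Hochberg method over all features of a contrast, with a threshold of 0.05. Before the data were examined, 27 gene lists with 459 entries were fixed. Of these entries 75 were measured, 2 entries were left out because their symbol belonged to another locus, 5 lists had at least 5 measured members and 3 had none. Those 5 lists (CLE peptide genes, defence-related WRKY factors, auxin response, iron deficiency, and abscisic acid and cold) were tested with camera at a preset correlation of 0.01. The named genes also followed a fixed rule. It took up to 12 increases and 12 decreases past the threshold per tissue, or, with fewer than 5 such genes, the 5 with the smallest p in each direction. It added up to 4 members per list, 6 genes in each direction for the difference, and 3 members each of the root and photosynthesis lists for the tissue comparison.

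The array labelled root DMSO replicate 3 resembled the shoot arrays and the array labelled shoot estradiol replicate 3 resembled the root arrays. Their labels were kept and no values were exchanged. Each result was also computed without these 2 arrays, a choice made after seeing the data, and the values from the remaining 10 arrays are named as such. Those 10 arrays left 2 arrays in each of the groups concerned. Alternatives covered intensity trends, array weights, a replicate block, filters on group means of 5 and 7, centring, quantile normalization, a fold threshold, single-gene features, plain t statistics, other list tests and the omission of each array.

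The fit was tested on simulated data with the spread of the 10 arrays and 50 changed features per size among 38408. All sizes were changed in the same simulated data, with noise independent between features. Many calls ease the Benjamini-Hochberg threshold, so the shares below do not give the recovery where few features change. For roots with 10 arrays it recovered 40%, 92%, 100% and 100% of log2 changes of 1, 2, 3 and 5, with 11 false calls. For shoots with 10 arrays it recovered 38%, 80%, 94% and 100%, with 8 false calls. With 12 arrays of which those 2 were exchanged in the simulation, it recovered 26%, 74%, 80% and 98% in roots and 0%, 0%, 2% and 0% in shoots.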

Results

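Expression was compared in 4 groups of 3 arrays each: roots with estradiol, roots with DMSO, shoots with estradiol and shoots with DMSO. The study asked which genes respond, in roots and in shoots, when CLE3 is induced in roots. Among the 10 arrays whose tissue label matched their profile, correlations across features were 0.984 to 0.989 within roots, 0.977 to 0.981 within shoots and 0.869 to 0.882 between the tissues. The array labelled root DMSO replicate 3 had a mean correlation of 0.981 with those shoot arrays and 0.874 with the root arrays. The array labelled shoot estradiol replicate 3 had a mean correlation of 0.986 with the root arrays and 0.874 with the shoot arrays. Every value from all 12 arrays below includes these 2 arrays in the groups that their titles give.

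**Figure D1:**
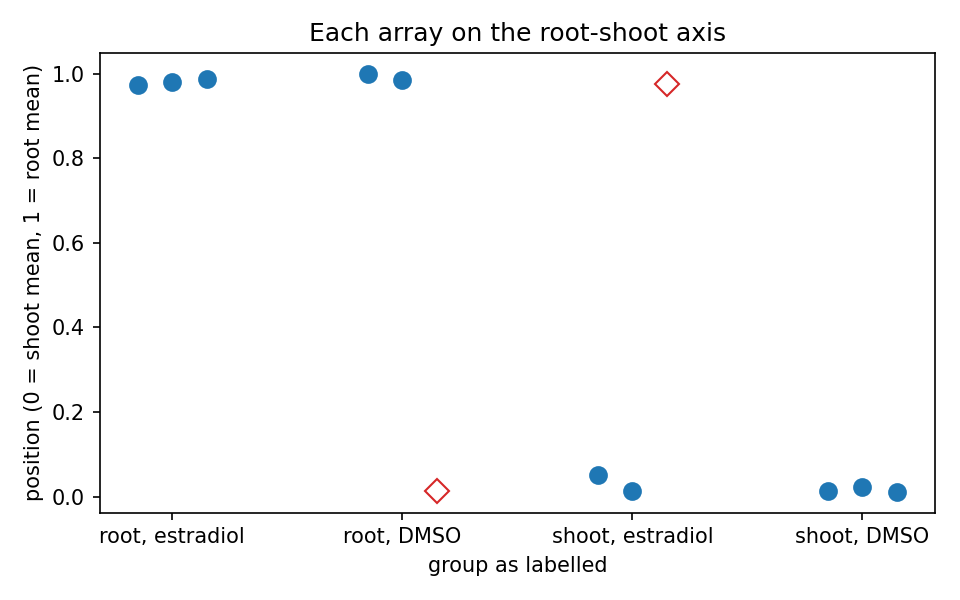
Position of each array (y axis, no unit) between the mean shoot profile at 0 and the mean root profile at 1, by labelled group (x axis), each array being left out of the means it was set against. Filled circles are 10 arrays and open diamonds the 2 arrays labelled root DMSO replicate 3, at 0.0142, and shoot estradiol replicate 3, at 0.976.

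In roots, 1 feature separated the treatments widely. Feature 13336474, which has no gene name here, had a log2 value of 12.17 ± 0.20 (SD, n = 3) with estradiol and 7.09 ± 0.37 (SD, n = 2) with DMSO on the 10 arrays. It rose by 5.08 on the log2 scale (SE 0.29), 33.9-fold, with a limma adjusted p of 0.00199. The call was lost without root DMSO replicate 1 (difference 4.82, adjusted p 0.0539) and with a replicate block (adjusted p 0.143). On all 12 arrays the difference was 5.53 (SE 0.59) with a limma adjusted p of 0.110. The feature lies outside the fixed naming rule and was chosen after its values were seen. In shoots its values were 5.16 ± 0.62 (SD, n = 2) with estradiol and 5.26 ± 0.28 (SD, n = 3) with DMSO on the 10 arrays.

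**Figure D2:**
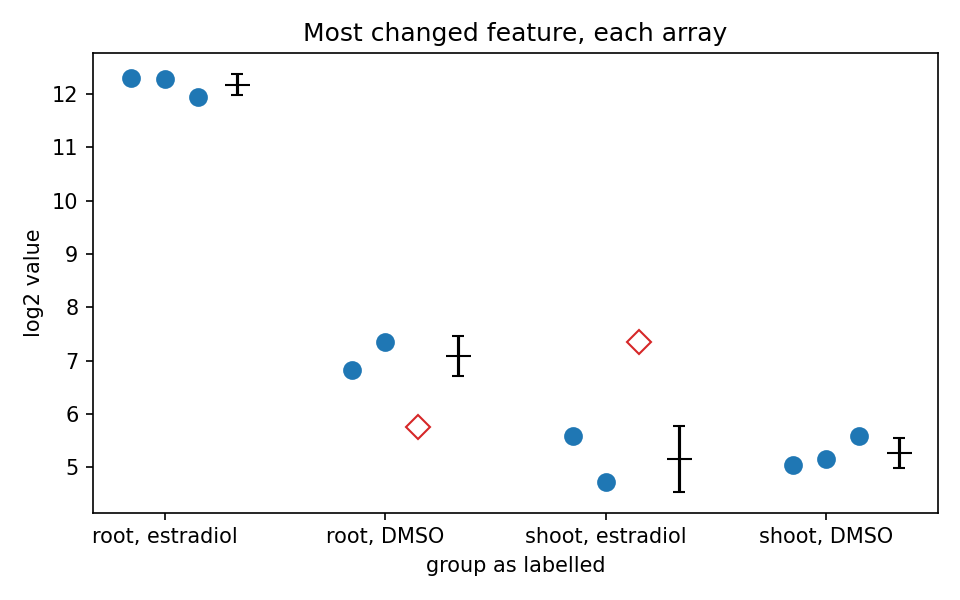
The log2 value of feature 13336474 on each array (y axis) by labelled group (x axis). Circles are the 10 arrays, bars their mean and SD, and open diamonds the 2 arrays left out of those means. The 3 root arrays with estradiol average 12.17, above every other array.

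The auxin-response list in roots had a camera adjusted p of 0.0241 on the 10 arrays, and adjusted p = 0.134 with an estimated correlation. Of 8 measured members 7 had negative differences and 1 a positive one, none passed the test singly, and the list median was -0.18. LBD29, a regulator of lateral root formation, had a difference of -0.53 (SE 0.17), and LBD16, which acts in the same process, -0.16 (SE 0.15). GH3.3, an auxin-conjugating enzyme, had -0.33 (SE 0.25). On all 12 arrays 4 members had positive and 4 negative differences, with a median of 0.05, a mean of 0.17 and a list adjusted p of 0.876. In shoots on the 10 arrays 6 of the 8 were negative, with a median of -0.19 and a list adjusted p of 0.615, and for the difference between the tissues the list had 0.552. Without root DMSO replicate 1 the adjusted p in roots was 0.437, and without root estradiol replicate 3 it was 0.123.

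**Figure D3:**
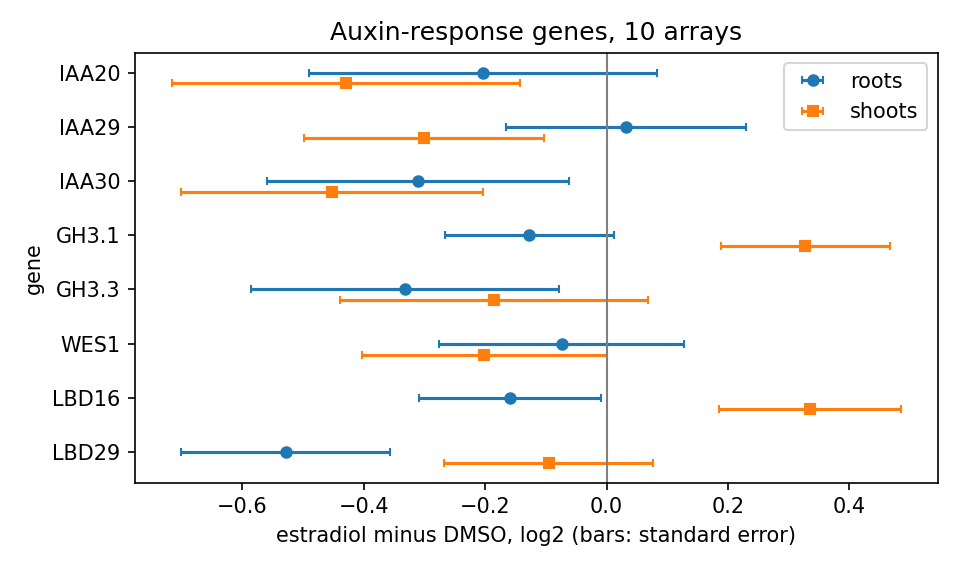
Difference between estradiol and DMSO (x axis, log2) for the 8 measured auxin-response genes (y axis) on 10 arrays, in roots (circles) and shoots (squares), with standard errors as bars. In roots 7 of the 8 points lie below 0, and LBD29 is lowest at -0.53.

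The other tested lists did not pass in roots on the 10 arrays. Of 5 iron deficiency genes 4 had positive differences, among them AT1G47395 at 0.73 (SE 0.57) and AT1G47400 at 0.66 (SE 0.53), with a list adjusted p of 0.0944. Of 11 CLE peptide genes 4 had positive and 7 negative differences, with CLE26 at 0.27 (SE 0.18) and a list adjusted p of 0.815. The 9 genes of this list whose symbol starts with CLE had a median level of 2.94. That lies near the lower quartile of the arrays (2.92 to 3.12), so the signs of such dim genes say little. The camera direction of this list was up although its median (-0.04) and mean (-0.01) were below 0. The 5 WRKY genes and the 5 abscisic acid and cold genes each had an adjusted p of 0.815. On 12 arrays the iron deficiency and WRKY lists had 0.651 and the CLE list and the abscisic acid and cold list 0.732. DFR, an enzyme of anthocyanin synthesis, had a difference of 0.64 (SE 0.17) in roots on the 10 arrays. There it was the 1 of 75 list members called when adjusted over the list alone, and over all features its adjusted p was 0.999. On 12 arrays its difference was -0.95 (SE 1.41), and 0 list members were so called in roots.

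Over all 12 arrays, 0 features passed in roots in limma, with 839 at an unadjusted p under 0.05. The 10 arrays gave 1 feature past the threshold, with 1440 at an unadjusted p under 0.05, and chance alone gives 1920. With the root groups of the 10 arrays fitted alone that count was 2121, so the 1440 depended on the spread shared with shoots. No named gene passed. Among named genes the smallest p-values on 12 arrays belonged to AT4G31196, with a difference of 1.11 (SE 0.22), and AT5G38390, with -0.60 (SE 0.14), both at an adjusted p of 0.900. On the 10 arrays AT4G37560 had 0.98 (SE 0.13) and AT1G02360 had -0.63 (SE 0.11), at adjusted p of 0.755 and 0.999. The median 95% interval reached 0.60 on either side of a difference on 12 arrays and 0.45 on 10.

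In shoots, which were not treated directly, no gene passed. STZ, a stress-related zinc finger repressor also called ZAT10, had 7.07 ± 0.65 (SD, n = 3) with estradiol and 5.49 ± 0.42 (SD, n = 3) with DMSO on 12 arrays. Its difference of 1.57 (SE 0.39) had a limma adjusted p of 0.800, and on the 10 arrays it was 1.28 (SE 0.39) with an adjusted p of 0.448. AT3G15450, a gene of the darkness and low sugar list, had 0.79 (SE 0.31) on 12 arrays and 0.92 (SE 0.35) on 10. These 2 genes were called on 12 arrays when adjusted over the list alone. On the 10 arrays 4 genes were so called: STZ, AT3G15450, WRKY22, a defence-related transcription factor, at 0.53 (SE 0.15), and the defensin gene PDF1.2 at -0.93 (SE 0.37). AT3G15450 and PDF1.2 were each the only measured member of their list, so adjusting over that list left their p-values unadjusted. Over all features 0 of the 75 list members passed on either set of arrays.

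All 5 measured WRKY genes had positive differences in shoots on the 10 arrays, with a median of 0.09 and a camera adjusted p of 0.260. On 12 arrays the WRKY, CLE and iron deficiency lists each had an adjusted p of 0.186, and the auxin list and the abscisic acid and cold list had 0.746. On 10 arrays the CLE, auxin and iron deficiency lists had 0.615, and the abscisic acid and cold list had 0.910. The iron deficiency list passed in shoots without shoot DMSO replicate 3, with an adjusted p of 0.00178 on the remaining 11 arrays and 0.00518 when the 2 doubted arrays were also left out. With an estimated correlation the adjusted p was 0.258 and 0.658, so these calls rest on the preset correlation. CLE22 had 0.70 (SE 0.21) and CLE26 -0.34 (SE 0.18) on the 10 arrays.

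In limma 0 features passed in shoots on 12 arrays, with 1820 at an unadjusted p under 0.05, and 0 passed on 10 arrays, with 3125. By p among named genes, AT2G32160 led the decreases on both sets, at -1.06 (SE 0.15) on 12 arrays and -0.92 (SE 0.12) on 10, with adjusted p of 0.759 and 0.215. AT1G27290 led the increases on 12 arrays at 0.53 (SE 0.13) and AT1G75600 on 10 arrays at 1.14 (SE 0.18). CYP71B25, a cytochrome P450 gene, had 1.08 (SE 0.18) and NHL22 1.03 (SE 0.18) on 10 arrays, both at an adjusted p of 0.236. Without shoot DMSO replicate 1 the 10 arrays gave 4 features past the threshold, and without shoot estradiol replicate 2 they gave 2.

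The effects in shoots and roots differed for 1 feature on the 10 arrays. Feature 13336474 had a difference (shoots minus roots) of -5.19 (SE 0.41) with a limma adjusted p of 0.0294, and -4.90 (SE 0.84) with an adjusted p of 0.719 on 12 arrays. On the 10 arrays it read 11.94 to 12.3 in roots with estradiol, 6.83 and 7.35 in roots with DMSO and 4.73 to 5.60 in shoots. No single array thus set the size of this difference. Among named genes AT2G26620 had -1.57 (SE 0.27) on 12 arrays and -1.44 (SE 0.26) on 10, at adjusted p of 0.719 and 0.492. AT1G07690 had 1.13 (SE 0.20) on 10 arrays at an adjusted p of 0.482, and AT5G55980 had 1.18 (SE 0.34) on 12 and 1.28 (SE 0.26) on 10. ROXY2, a glutaredoxin gene, had -1.02 (SE 0.28) on 12 arrays at an adjusted p of 1. In limma 0 features passed on 12 arrays, with 799 at an unadjusted p under 0.05, against 1 and 1828 on 10 arrays. The call for feature 13336474 was lost without any one of 8 of the 10 arrays, at an adjusted p of 0.0810 to 0.232, and with a replicate block, at 0.759. It held without root estradiol replicate 3 (adjusted p 0.0469), where the count was 23, and without shoot estradiol replicate 1 (0.0238).

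Root and shoot responses were compared across 16505 genes, which are not independent replicates. On 12 arrays Pearson's r was 0.822 and Spearman's rho 0.660. On the 10 arrays r was 0.123 and rho 0.117. Without root DMSO replicate 3 alone r was -0.0274, and without shoot estradiol replicate 3 alone it was 0.103, so the 0.822 depended on both arrays. The 12-array response correlated with the root minus shoot difference of the 10 arrays at r = 0.872 in roots and 0.910 in shoots. The slopes on that difference were 0.300 and 0.340. The 10-array responses, which share DMSO arrays with that difference as well, correlated with it at -0.176 and 0.138.

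Root and shoot under DMSO differed in the genes that mark each organ once the 2 arrays were left out. All 4 measured root genes were higher in roots on the 10 arrays. BGLU21 and BGLU22, beta-glucosidases, were higher by 6.94 (SE 0.31) and 7.25 (SE 0.42), NAI2, a protein of ER bodies, by 1.95 (SE 0.14), and PYK10, an abundant root beta-glucosidase, by 1.39 (SE 0.13). All 4 measured photosynthesis genes were lower in roots. The Calvin cycle enzymes SBPASE and PRK differed by -3.87 (SE 0.28) and -3.18 (SE 0.30), Rubisco activase RCA by -2.60 (SE 0.37) and the light-harvesting protein LHCB4.1 by -2.43 (SE 0.17). Adjusted p was 0.000508 for RCA and lower for the other 7.

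**Figure D4:**
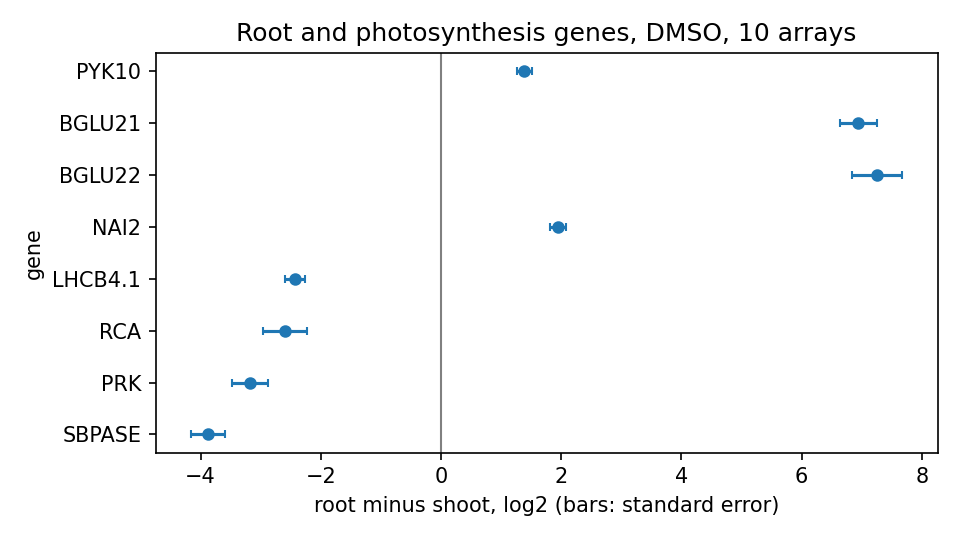
Root minus shoot difference under DMSO (x axis, log2) of 4 root genes and 4 photosynthesis genes (y axis) on 10 arrays, with standard errors as bars. The root genes lie between 1.39 and 7.25 and the photosynthesis genes between -3.87 and -2.43.

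On all 12 arrays the same tissue comparison gave 0 features past the threshold in limma, with 6642 at an unadjusted p under 0.05. BGLU21 then averaged 7.88 ± 4.42 (SD, n = 3) in roots with DMSO, against 3.49 ± 0.53 (SD, n = 3) in shoots. SBPASE averaged 8.61 ± 2.32 (SD, n = 3) in roots with DMSO and 11.16 ± 0.03 (SD, n = 3) in shoots. The 10 arrays gave 15038 features, 7394 higher in roots and 7644 higher in shoots. Without root DMSO replicate 3 alone the count was 9695.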

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

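The tests of the 2 arrays, of the most changed feature and of the splits of 12 arrays were chosen after the results were seen, as was the comparison of bright features between the tissues. The other 3 tests on low p-values in shoots were written before theirs. Feature 13336474 differed in its response between the tissues on the 10 arrays, with an interaction of -5.19 (SE 0.41) and a limma adjusted p of 0.0294.

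The rise of feature 13336474 in roots was set against an artefact of a single array. Leaving out each of the 5 root arrays in turn gave a rise of at least 4.82 on the log2 scale, which argues against one array as its cause. A response in the treated organ stays open. The feature was picked for its rise in roots, so the difference between the tissues (adjusted p 0.0294) partly restates that rise. That call was lost without any one of 8 of the 10 arrays (adjusted p 0.0810 to 0.232) and with a replicate block (0.759), as was the call in roots with the block (0.143). Single values on the 10 arrays were 11.94 to 12.3 in roots with estradiol, 6.83 and 7.35 in roots with DMSO and 4.73 to 5.60 in shoots. The losses therefore concern the adjusted p more than the size of the difference. Whether the feature measures the induced transgene stays open, because no gene name was available for it. The choice of the feature from 38408 and the test used the same arrays.

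The 2 arrays that lay with the other tissue were set against 3 explanations. Their mean correlations with the other tissue, 0.981 for root DMSO replicate 3 and 0.986 for shoot estradiol replicate 3, lay within the range of the arrays there, so an exchange of their labels is a candidate explanation. Their positions of 0.0142 and 0.976 between shoot at 0 and root at 1 argue against a mixture of RNA from both organs. The lower of their highest correlations with another array, 0.983, argues against a failed hybridisation. Feature 13336474 read 7.35 on the array labelled shoot estradiol replicate 3, near the 7.09 ± 0.37 (SD, n = 2) of root DMSO and below the 12.17 ± 0.20 (SD, n = 3) of root estradiol, as an exchange of whole labels, treatment included, would give. This is 1 feature, and no array was reassigned from it. At which step an exchange would have happened stays open, and no biological explanation was tested.

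Low p-values were more frequent in shoots than in roots on the 10 arrays, with 3125 against 1440 features at an unadjusted p under 0.05. That fit shared 1 spread between the tissues, although shoots varied more (median SD 0.221 against 0.184 in roots). With each tissue fitted alone the counts were 2414 in shoots and 2121 in roots, so most of the gap went with the shared spread. Leaving out each shoot array left at least 2595, above the 1920 of chance. The lowest count among the other splits of the 5 shoot arrays into 3 and 2, 1945, also lay above 1920. Staying above 1920 therefore does not decide whether 1 array set the excess. Of the 10 splits of the 5 shoot arrays into 3 and 2, 3 gave at least as many as the real one, itself included, with a highest other count of 3522, so structure that does not follow the treatment could account for the excess. Among features with a mean of at least 5 the share was 4.97% in shoots and 2.33% in roots, and among the others 11.4% and 5.19%. The 4.97% lay just under the limit of 5% set beforehand for dim features as the cause. In a fit of only the features with a group mean of at least 5, however, the share in shoots was 7.39%. Whether the excess over chance in shoots lay among dim features therefore depended on the fit and is not decided. The limit of 5% also does not compare the tissues. Each of the 10 arrays was also left out in turn. The lowest share of the brighter features in shoots (3.40%) stayed above the highest in roots (2.78%), by 0.613 percentage points. This argues against dim features as the whole cause of the gap between the tissues in that fit, but not of the excess over chance. Brighter features also varied more in shoots (median SD 0.153 against 0.138 in roots), so the shared spread may enter this gap too. An indirect response of shoots to the root treatment stays open.

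Splits of the 12 arrays were counted for each contrast. In roots, in shoots and between the tissues under DMSO, the 6 arrays allow 10 splits, too few for a share under 0.05, and in each contrast the real split gave 0 features and the highest other 0, so that 10 of 10 gave as many. For the difference between the tissues 100 splits were drawn, 100 of them gave at least the real 0, and the highest other gave 4. With a real count of 0 every split gives at least as many, so these counts say nothing about chance.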

How the results depend on the processing

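Omitting 2 arrays, and every setting on the remaining 10, was chosen after seeing the data. On 12 arrays, the counts of 0 in roots, in shoots, for the difference and for the tissue comparison stayed at 0 with trends, filters, centring, quantile normalization, a fold threshold, single-gene features and plain t statistics, and with the compared groups alone in all but the difference, where that was not run. Array weights, which gave the 2 doubted arrays weights of 0.122 and 0.129, gave 1 in roots, 2 for the difference and 16916 between tissues. The 10 arrays gave 1, 1 and 15038. Leaving out single arrays gave 0 to 9695 between tissues, the highest without root DMSO replicate 3, and 0 elsewhere.

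With a replicate block the 12-array counts were 0 in all 4 contrasts. The numbers are not stated to mark a shared batch, and deviations of same-numbered arrays on the 12 arrays correlated between -0.0182 and 0.0555, around means that include the 2 doubted arrays. On the 10 arrays they correlated at 0.118 and -0.00178 in roots and at 0.0754 and 0.0617 in shoots. Not every pair exceeded 0.1, so the numbers were not taken as pairs. In each tissue the group left with 2 arrays has deviations that mirror each other. The correlations within a tissue are therefore not independent, and pairing is not excluded. On the 10 arrays the block gave 0 in roots, where feature 13336474 kept a difference of 5.06 with an adjusted p of 0.143, 0 for the difference, 0 in shoots and 14457 between tissues. List counts with the block were 0 on 12 arrays, and 1 in roots and 1 in shoots (iron deficiency, adjusted p 0.00625) on 10, both 0 with an estimated correlation.

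On the 10 arrays, single-gene features gave 0 in roots, 0 for the difference and 7692 between tissues, because fewer features were tested and feature 13336474 is unnamed. Leaving out single arrays gave 0 to 1 in roots, 0 to 4 in shoots, 0 to 23 for the difference and 11538 to 14232 between tissues. A group left with 1 array was assumed to vary like the others.

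For gene lists, the 10 arrays gave 1 in roots, against 0 on 12. On those 10 an estimated correlation gave 0, root arrays alone gave 2 and leaving out single arrays 0 to 2. In shoots leaving out single arrays gave 0 to 1 on 12 and on 10 arrays, the 1 being iron deficiency without shoot DMSO replicate 3. With an estimated correlation leaving out single arrays gave 0 throughout, and fry gave 1 only for auxin in roots, without root DMSO replicate 2 (adjusted p 0.0231). The correlation of root and shoot responses, 0.822 on 12 arrays, was -0.0274 to 0.860 when single ones of the 12 were left out. The lowest, without root DMSO replicate 3, changed sign but lay near 0. It was 0.123 on the 10 arrays, and 0.123 there with a group mean of at least 5. The cause of these changes was not tested beyond the 2 arrays. The planned test of the CLE3 level was not run, because no feature named the gene, and signal over background was not analysed here.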

Other observations

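The comparisons on 10 arrays, and the families named by the start of the gene symbol, were chosen after seeing the data. All values here are from the 10 arrays unless 12 are named. On 12 arrays 0 of the 75 list members passed between tissues, and EXPA7 and EXPA18 had 1.70 (SE 0.60) and 3.77 (SE 1.38), both at an adjusted p of 0.273. Lists with fewer than 5 measured members had no list test, and their genes are given singly. Of all 16505 genes, 3667 were higher in roots and 3370 higher in shoots under DMSO. Counts of passing list members below are therefore not by themselves a trait of a list. The root hair expansins EXPA7 and EXPA18, 2 of 9 listed genes, were higher in roots than in shoots under DMSO, by 2.21 (SE 0.18) and 5.29 (SE 0.55). BBM, a regulator of meristem identity and the 1 measured gene of 9 listed, was higher by 2.88 (SE 0.30). Of 8 auxin-response genes 4 were higher in roots, 1 was lower and 3 did not pass, with LBD29 at 3.71 (SE 0.17), LBD16 at 3.57 (SE 0.15) and IAA29 at -1.19 (SE 0.20). The auxin list had a camera adjusted p of 0.110. Among 5 WRKY genes 2 passed, WRKY6 at 2.51 (SE 0.11) and WRKY29 at 1.83 (SE 0.25), with a list adjusted p of 0.160.

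Of 13 listed anthocyanin genes 4 were measured and were higher in shoots, with DFR at -5.22 (SE 0.17) for root minus shoot. Of 16 listed cytokinin genes 2 were measured and were higher in shoots, RR16 at -4.79 (SE 0.26) and ARR15 at -2.26 (SE 0.31). Of 4 sugar and starch genes 3 were lower in roots, among them the sucrose transporter SWEET11 at -4.12 (SE 0.28). Of 11 CLE peptide genes 4 were lower in roots, among them CLE26 at -0.92 (SE 0.18), and 7 did not pass, with a list adjusted p of 0.299. Abscisic acid and cold genes went both ways, with LTI30 at 3.63 (SE 0.17) and COR15A at -4.05 (SE 0.74), and a list adjusted p of 0.213. The iron deficiency list had 0.846.

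Of 35 groups of genes sharing the start of their symbol, each with at least 8 measured genes, 0 passed in roots, 0 in shoots and 0 between tissues. Such a group need not be a single gene family, as the GH group holds both GH3 and GH9 genes. In roots the expansin family had 13 measured genes, a median of 0.15 and the smallest adjusted p, 0.192. With an estimated correlation that adjusted p was 0.737. The median of this family in shoots was also 0.15, so the shift was not particular to roots.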
